A study of Mus musculus with 24 samples.

How the data were processed

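RNA was sequenced from 5 mouse tumour cell lines in 24 libraries, which form 8 groups of 3 replicates. Total RNA came from the mammary tumour lines 4T1, 4T07 and 67NR and from the melanoma lines B16F10 and B16F0, grown in D10F medium and extracted with a Norgen total RNA kit. Cell-free RNA came from medium in which 4T1, 4T07 and 67NR cells had been starved overnight (Opti-MEM), concentrated on a 10 kDa filter and extracted with a Norgen plasma and serum kit. Both kinds of RNA were made into stranded total RNA libraries (TruSeq), which keep transcripts with and without a poly(A) tail. The labels call 4T1 and B16F10 highly metastatic and 4T07, 67NR and B16F0 poorly metastatic.

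The read processing was done by the authors before deposit. The labels name cutadapt 2.3, BWA 0.7, featureCounts 1.6.0, DESeq2 1.22 and the mouse build mm10 without saying in which order or for which step each was used. How reads with several alignments were counted, whether strand was used in counting, and from which features the size factors were computed is not given in the sources used here. The deposited values are raw counts in 3 tables, each with 123 named endogenous retrovirus (ERV) entries. The authors also deposited normalised signal for the same entries, which are counts divided by 1 size factor per library: raw divided by normalised was constant within each library, and these factors differed from those computed from the ERV entries alone. The deposited comparison tables, 7 in number, hold the authors' DESeq2 results, with a mean normalised signal, a log2 fold change, its log2 standard error, a Wald score, a p-value and an adjusted p-value. The adjusted p-values in them equal Benjamini-Hochberg values over these entries alone. In total RNA they are given for 77 entries for 4T1 over 67NR, 122 for 4T1 over 4T07 and 107 for 4T07 over 67NR. They are given for 119 for B16F10 over B16F0, and in cell-free RNA for 108, 118 and 118 for the 3 mammary comparisons in the same order. Counts from these tables are over those entries and not over the entries tested with edgeR. Of the 123 entries, 26 carry a single repeat name and 97 carry several names joined by commas, such as ERVB4_3-LTR_MM,ERVB4_3-I_MM-int. What a joined name stands for is not given in the sources used here, nor is any genome position, so that each entry is reported by its name as the files give it.

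Differences were tested on the raw counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust estimation, filterByExpr at its defaults, adjusted p under 0.05), with TMM scaling over the ERV entries. This scale measures each entry relative to the other ERV entries and is called the ERV-only scale. It removes a change shared by all entries, so that the same fits were also run with the authors' size factors, called the authors' scale. The authors' size factors were set as an alternative before the data were examined. Reporting calls on that scale as results of their own, and running alternatives on it, was decided afterwards. All 9 libraries of the 3 mammary lines of 1 RNA fraction shared an estimate of the spread, the 6 melanoma libraries were fitted alone, and the 18 mammary libraries were fitted together on the ERV-only scale for the difference of line effects between cell-free and total RNA. The edgeR fit also draws the spread of an entry toward that of the other entries, which are not independent. Very small edgeR p-values therefore do not rest on the replicates of an entry alone. Standard errors of edgeR fold changes were taken from the test statistic. Summed normalised counts and the shares of counts were compared with a two-sided exact permutation test, for which 0.1 is the smallest p that 3 libraries against 3 can give. The error of the log2 difference of 2 summed counts is the standard error over libraries.

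Lists of ERV families were fixed before the data were examined, as were the tests, the rule for named entries and the other alternatives. Of the 12 lists, the ETn/MusD list, read here as names with ERVB7, matched 15 entries and the list of internal regions matched 73. A joined entry counts as an internal region by its last name alone. ERVB4_3-LTR_MM,ERVB4_3-I_MM-int is thus in that list and ERVB4_3-I_MM-int,ERVB4_3-LTR_MM is not. The lists IAP, MMERVK10C, MMTV, MuLV, VL30, GLN, MuRRS, MERVL, MaLR and shared names matched 0 entries and were not analysed here. Groups by name (ERVB2, ERVB3, ERVB4, ERVB5, ERVB7 as first name, ERVL, ERV3-16 and single-name entries) were added after the names had been seen. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, then estimated) and with fry. The named entries of a line comparison are, among entries past the threshold with a mean of at least 10 counts in 1 of the 2 lines and no overlap of single libraries, the 10 that rose and the 10 that fell most, then the 5 most abundant entries and the up to 4 members of each list with the largest change either way. For the cell-free and total RNA contrasts they are the 5 past the threshold with the largest change each way. An entry outside that rule was chosen after its values had been seen.

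The alternatives were DESeq2 1.42.0, RLE factors, no TMM factor, no filter on low counts, a mean of 50 or more counts, a replicate block, a fit of only the 6 libraries compared, and each library left out in turn. Leaving 1 library out leaves 2 in its group, with the spread still estimated over all libraries of the fit. Counting all splits of the 6 libraries gives 10, and for the contrasts over 18 libraries 100 distinct regroupings, the real one included, were drawn from 200 for the differences of line effects and from 4000 for cell-free against total RNA. The difference between fractions in summed counts was set against all 400 regroupings within the fractions, which assume no line difference in either fraction. Replicates 1 to 3 carry the same numbers in all groups. Among the 7 pairs of groups compared, same-numbered libraries deviated together with every correlation over 0.1 only for cell-free 4T07 and 4T1 (0.152 to 0.304). There replicates 2 and 3 correlated as much across numbers (0.182 and 0.166). The correlations thus part replicate 1 from replicates 2 and 3, and whether the numbers pair the libraries is unsure. With the replicate block, 5 entries passed in that comparison on the ERV-only scale in place of 4, and 1 passed on the authors' scale in place of 0.

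ERV counts per library ranged from 2716 to 108679, and these are the only depths the files give. Shares of counts carry Wilson 95% intervals, which cover counting error only, since the reads have no molecular identifiers. Entries with no counts in all 3 libraries of a group are given as a bound against 3 counts over the group. The edgeR test was run on simulated data with the depths of these libraries and their spread on the ERV-only scale. In total RNA it recovered 5 of 7 entries changed 1.5-fold, 6 of 7 changed 2-fold and 6 of 6 changed 4-fold for 4T1 against 67NR (92 entries run), 5, 5 and 7 of 7 each for 4T1 against 4T07 (93), 6, 6 and 7 of 7 each for 4T07 against 67NR (93), and 5 of 6, 5 of 5 and 7 of 7 for B16F10 against B16F0 (55). In cell-free RNA it recovered 1, 4 and 4 of 7 each for 4T1 against 67NR (90), 2 of 6, 7 of 7 and 7 of 7 for 4T1 against 4T07 (89), and 0 of 7, 1 of 6 and 6 of 7 for 4T07 against 67NR (89). Among unchanged entries it called 1 of 69 in each cell-free comparison with 4T07 and 0 in the other comparisons. When all entries were raised 4-fold alike, outside size factors recovered all of the 93 or 58 entries in the total RNA comparisons, 83 and 85 of 92 for 4T1 and 4T07 against 67NR in cell-free RNA and 92 of 92 for 4T1 against 4T07. TMM recovered 1 of 93 for 4T07 against 67NR in total RNA and 0 in the other 6 comparisons. The outside size factors were here the very library sizes of the simulation, so that their recovery is built in. The spread on the authors' scale was not simulated. There the edgeR coefficient of variation common to the entries was 0.57 in the melanoma and 0.55 in the cell-free libraries. The recovery thus does not show what the authors' scale can detect. Further computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.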

Results

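Reads from 123 endogenous retrovirus (ERV) entries were counted in total RNA of 5 mouse tumour lines and in cell-free RNA from the medium of 3 of them, with 3 libraries per group. The lines 4T1, 4T07 and 67NR are sublines of 1 mouse mammary tumour, and B16F10 and B16F0 are melanoma lines. In total RNA the libraries held 73091 to 108679 ERV counts for 4T1, 23105 to 32017 for 4T07, 22151 to 47844 for 67NR, 11935 to 21399 for B16F10 and 2847 to 7112 for B16F0. In cell-free RNA they held 13247 to 54824 counts for 4T1, 40699 to 65148 for 4T07 and 2716 to 5465 for 67NR. The total number of reads per library is not given in the sources used here. The deposited column names of the 4T1 total RNA libraries carry a tag, RD2, that those of 4T07 and 67NR lack. What it stands for is not given, so that anything it marks cannot be told apart from the line. The 5 most abundant entries of a group took between 35.5% (B16F10) and 62.5% (67NR cell-free RNA) of its ERV counts. ERV profiles ranked the entries alike in all groups, with Spearman correlations across the 123 entries of 0.891 to 0.992 over the 28 pairs of groups. Entries are not independent replicates.

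The first question was whether the RNA of these 123 entries as a whole was more abundant in the highly metastatic line. No entry carries a name from the lists for IAP, MMERVK10C, MMTV, MuLV, VL30, GLN, MuRRS, MERVL or MaLR, so that the sums leave these families out. Summed normalised counts in cell-free RNA were 45633 ± 2328 for 4T1, 25462.5 ± 6376 for 4T07 and 5685 ± 3959 for 67NR (SD, n = 3 each). Ratios of sums are given here as ratios of geometric means over libraries, which differ from the ratios of these means. By them 4T1 was 9.29 times as high as 67NR (log2 difference 3.22 ± 0.54, SE) and 1.83 times as high as 4T07 (0.87 ± 0.20), and 4T07 was 5.09 times as high as 67NR (2.35 ± 0.57). In total RNA the mammary lines were closer, with 54539 ± 1914 for 4T1, 37961 ± 695 for 4T07 and 43716.5 ± 8310.3 for 67NR. There 4T1 was 1.26 times as high as 67NR (0.34 ± 0.16) and 1.44 times as high as 4T07 (0.52 ± 0.033). B16F10 held 16474 ± 9284 and B16F0 3817 ± 1835, with geometric means in a ratio of 4.15 (2.05 ± 0.60).

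In 6 of these 7 comparisons the 3 libraries of 1 line all lay above the 3 of the other, a separation that chance gives in 10% of comparisons of 3 against 3. The exception was 4T07 against 67NR in total RNA, with a ratio of geometric means of 0.879 (log2 difference -0.19 ± 0.16) and overlapping libraries. The two-sided exact permutation p was 0.1 in the other 6 and 0.4 in that one, and 0.117 and 0.4 after Benjamini-Hochberg adjustment over the 7. No comparison of 3 libraries with 3 can give less than 0.1, in this permutation test, so that by it none of these differences could pass a threshold of 0.05. With each library left out in turn the ratio stayed between 7.49 and 13.4 for 4T1 over 67NR in cell-free RNA and between 3.09 and 5.49 for B16F10 over B16F0. It stayed between 1.16 and 1.39 for 4T1 over 67NR in total RNA. These sums rest on the size factors of the authors, whose origin is not given in the sources used here.

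**Figure D1:**
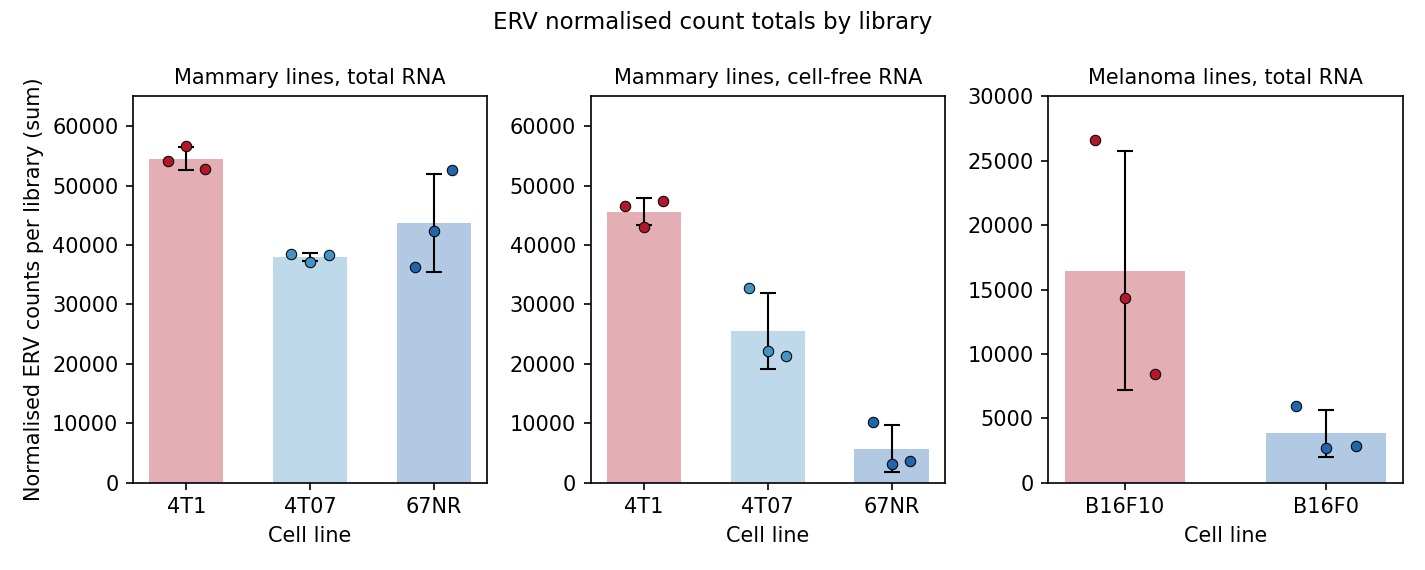
Summed normalised ERV counts per library (vertical axis, normalised counts) for each line, with bars for the mean, error bars for the SD and points for the 3 libraries. In cell-free RNA the means are 45633 for 4T1, 25462.5 for 4T07 and 5685 for 67NR, whereas in total RNA 67NR has 43716.5.

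Single entries were compared on 2 scales that answer different questions. The ERV-only scale measures an entry relative to the other ERV entries, and the authors' scale measures it relative to whatever set the authors' size factors. The median log2 fold change over the tested entries in total RNA was 0.012 on the ERV-only scale and 0.27 on the authors' scale for 4T1 over 67NR, -0.019 and 0.58 for 4T1 over 4T07, and -0.0018 and -0.34 for 4T07 over 67NR. For B16F10 over B16F0 it was -0.068 and 2.26. In cell-free RNA it was 0.29 and 3.71 for 4T1 over 67NR, -0.019 and 1.07 for 4T1 over 4T07, and 0.28 and 2.62 for 4T07 over 67NR. In the cell-free comparisons with 67NR, 5 entries had no counts in all 3 libraries of 67NR. With these held at 3 counts over the group the medians on the authors' scale were 3.61 for 4T1 and 2.59 for 4T07. A direction given for an entry below is relative to the other ERV entries unless the authors' scale is named. On the ERV-only scale, unless stated, every library of 1 line lay above every library of the other for each entry named as higher or lower between lines. Overlap of single libraries was not checked for entries on the authors' scale.

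**Figure D2:**
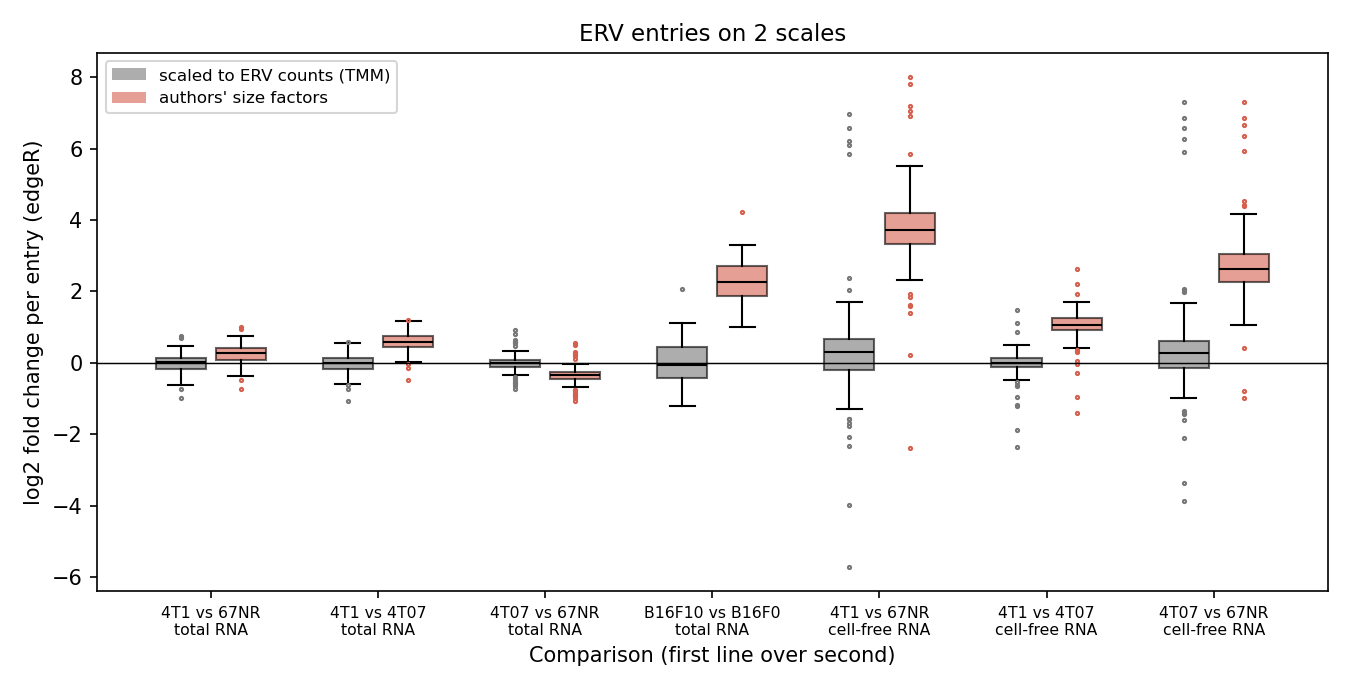
Log2 fold changes of the tested ERV entries (vertical axis) in the 7 comparisons of lines, as boxes over entries for the ERV-only scale and for the authors' scale. The median for B16F10 over B16F0 moves from -0.068 to 2.26 and that for 4T1 over 67NR in cell-free RNA from 0.29 to 3.71, and the outermost points in cell-free RNA include fitted values of entries with no counts in 67NR.

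In total RNA, 4T1 and 67NR differed in a few entries by less than 2-fold. The joined entry ERVB4_1C-LTR_Mm,ERVB4_1-I_MM-int,ERVB4_1-I_MM-int,ERVB4_1-I_MM-int was lower in 4T1 by a log2 change of -0.73 ± 0.11 (SE, n = 3 each; edgeR adjusted p 7.28e-10), and on the authors' scale by -0.49 with an adjusted p of 0.0840. ERVB4_3-LTR_MM,ERVB4_3-I_MM-int was higher, by 0.48 ± 0.11 (edgeR adjusted p 1.92e-04) and by 0.72 on the authors' scale, and so was ERVB7_4-LTR_MM, by 0.31 ± 0.070 (edgeR adjusted p 1.92e-04) and 0.57. ERVB4_1-I_MM-int,ERVB4_1-I_MM-int,ERVB4_1-I_MM-int was lower by -0.62 ± 0.12 and ERVB3_1-I_MM-int by -0.31 ± 0.067, which on the authors' scale were -0.36 and -0.041. These 5 calls, of the 12 of the named entries, were kept without each library in turn. ERVB7_1-LTR_MM, which took 9.49% of ERV counts in 4T1 and 8.28% in 67NR, was higher by 0.25 ± 0.06, and its call was lost without 67NR replicate 3 (0.17).

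Of 93 entries tested between these lines with edgeR, 6 were higher and 7 lower in 4T1, against 32 at an unadjusted p under 0.05 and 7 past the threshold in DESeq2. The 13 became 6 without 4T1 replicate 2 and 8 without 67NR replicate 3. With the authors' size factors 8 were higher and 0 lower (edgeR, 30 at an unadjusted p under 0.05), and this became 2, 0 and 3 without 4T1 replicates 1, 2 and 3, 0 without 67NR replicate 2 and 58 without 67NR replicate 3. Of the entries in the authors' deposited table (DESeq2), 3 are higher and 0 lower.

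Against 4T07, 4T1 total RNA held more of nearly every entry on the authors' scale and a like mix of entries. ERVB7_1-LTR_MM was lower in 4T1 relative to the other entries, by -0.38 ± 0.059 (SE, n = 3 each; edgeR adjusted p 3.04e-08), and on the authors' scale this flipped to 0.23 with an adjusted p of 0.125. Its call was kept without each library. ERVB4_1C-LTR_Mm was lower by -0.58 ± 0.10 (edgeR adjusted p 0.00471; 0.026 on the authors' scale), but the call was lost without 4T07 replicate 1 (-0.57), 2 (-0.54) or 3 (-0.63) or 4T1 replicate 2 (-0.58). ERVB7_4-LTR_MM was higher by 0.28 ± 0.073 (edgeR adjusted p 0.00471; 0.88 on the authors' scale), lost without 4T07 replicate 2 (0.24) or 3 (0.26) or 4T1 replicate 3 (0.24). Thus 1 entry was higher and 2 were lower of 93 tested with edgeR, with 18 at an unadjusted p under 0.05 and 2 in DESeq2. The 3 became 1 without 4T07 replicate 2 or 3. Without the TMM factor 15 were higher and 3 lower. With the authors' size factors 63 were higher and 0 lower (edgeR, 67 at an unadjusted p under 0.05), 38 without 4T07 replicate 2, and the authors' deposited table has 44 and 0.

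The poorly metastatic lines 4T07 and 67NR also differed from each other in total RNA. ERVB7_1-LTR_MM took 11.7% ± 0.254 of ERV counts in 4T07 and 8.28% ± 0.901 in 67NR (SD, n = 3), a log2 change of 0.63 ± 0.061 (SE; edgeR adjusted p 9.69e-21), and 0.31 on the authors' scale with an adjusted p of 0.125. That edgeR p and SE draw on a spread estimated over many entries, so that the p is far smaller than 3 libraries per line alone could give. ERVB4_3-LTR_MM,ERVB4_3-I_MM-int was higher by 0.58 ± 0.13 (edgeR adjusted p 2.20e-04; 0.24 on the authors' scale). Both calls were kept without each library. ERVB4_1C-LTR_Mm was higher by 0.81 ± 0.11 (edgeR adjusted p 2.20e-04; 0.50 on the authors' scale), a call lost without 4T07 replicate 1 (0.81) or 2 (0.78). The 3 entries that were lower, among them ERVB3_1-I_MM-int at -0.32 ± 0.076, all lost their calls without 4T07 replicate 1, where ERVB3_1-I_MM-int stood at -0.27.

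Of 93 entries tested with edgeR between 4T07 and 67NR, 3 were thus higher and 3 lower, with 13 at an unadjusted p under 0.05 and 6 in DESeq2, and 2 in all without 4T07 replicate 1. Without the TMM factor 3 were higher and 10 lower. On the authors' scale 1 was higher and 10 lower (edgeR, 33 at an unadjusted p under 0.05). These 11 became 0, 2 and 5 without 4T07 replicates 1, 2 and 3, and 54, 4 and 6 without 67NR replicates 1, 2 and 3. The authors' deposited table counts 1 as higher and 3 as lower.

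Between the melanoma lines, nearly every entry was higher in B16F10 on the authors' scale, and the mix of entries differed as well. ERVB4_2-LTR_MM was higher in B16F10 relative to the other entries, by 1.05 ± 0.25 (SE, n = 3 each; edgeR adjusted p 0.00454; 515 against 52 counts over the libraries), and by 3.27 on the authors' scale. ERVB2_1A-I_MM-int was lower relative to the others by -1.11 ± 0.18 (edgeR adjusted p 6.69e-04) and ERVB3_1-I_MM-int by -1.01 ± 0.18 (edgeR adjusted p 0.00297), but on the authors' scale they were higher, at 1.29 and 1.40 with adjusted p of 0.0935 and 0.0839. In the same way ERVL-B4-int,ERVL-B4-int (-1.04 ± 0.25), ERVB7_2-LTR_MM (-0.77 ± 0.18) and ERVL-int (-0.60 ± 0.15) were lower relative to the others and flipped to 1.29, 1.59 and 1.84 on the authors' scale. These 6 of the 22 calls of named entries were kept without each library. ERVB7_1-LTR_MM was higher by 0.50 ± 0.15 (edgeR adjusted p 0.0128; 2.78 on the authors' scale), a call lost without B16F0 replicate 2 (0.45) or 3 (0.41).

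With edgeR, 11 of 58 entries tested were higher and 12 lower in B16F10 than in B16F0, with 26 at an unadjusted p under 0.05 and 18 in DESeq2, which left 61 entries without an adjusted p. With no filter 3 were higher and 11 lower, and with the replicate block 4 and 8. The 23 became 9 without B16F0 replicate 2 and 13 without B16F10 replicate 1. By the authors' size factors 53 were higher and 0 lower (edgeR, 53 at an unadjusted p under 0.05), and this became 0 without B16F0 replicate 2, 1 without B16F0 replicate 3, and 18 and 15 without B16F10 replicates 1 and 2. The authors' deposited table counts 94 as higher and 0 as lower, of 119 entries with an adjusted p. B16F0 replicates 2 and 3, with 2929 and 2847 counts, did not differ beyond sampling noise (chi-square p 0.0639 over entries with at least 20 counts), which held for no other of the 24 pairs of replicates. With so few counts the test has little power. Per degree of freedom its chi-square (42.6 on 30) was larger than that of total RNA 4T07 replicates 1 and 2 (110 on 85, chi-square p 0.0346). It therefore does not show that the B16F0 libraries are repeats, and the labels call these libraries separate replicates. Were they repeats of 1 culture, B16F0 would have 2 independent libraries and the errors and p-values given for B16F10 over B16F0 would be too small. Without replicate 2 or 3, 9 and 17 entries passed on the ERV-only scale and 0 and 1 on the authors' scale.

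In cell-free RNA, 4T1 held far more of most entries than 67NR on the authors' scale, and ERVB7_2-LTR_MM stood apart. It took 24.8% ± 12.4 of ERV counts in 67NR, 2.79% ± 0.214 in 4T1 and 2.53% ± 0.152 in 4T07 (SD, n = 3 each). In the 67NR libraries the share was 11.03% (Wilson 95% interval 10.2 to 11.9), 28.5% (26.8 to 30.2) and 34.9% (33.3 to 36.7). Relative to the other entries it was lower in 4T1 than in 67NR by -3.98 ± 0.54 (SE; edgeR adjusted p 3.07e-04), but on the authors' scale the change was 0.21 with an adjusted p of 0.780. Its normalised count in cell-free RNA was 1269 ± 85.7 in 4T1 and 1101 ± 180 in 67NR, while the geometric means of the sums over all entries differed 9.29-fold. The joined entry ERVB4_1C-LTR_Mm,ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int was lower in 4T1 on both scales, by -5.71 ± 0.56 (edgeR adjusted p 1.51e-05) and -2.38 (edgeR adjusted p 0.00409), with 18 counts over the 4T1 libraries and 68 over the 67NR libraries. Both calls on the ERV-only scale were kept without each library, though that of the joined entry moved to -6.81 without 4T1 replicate 2.

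**Figure D3:**
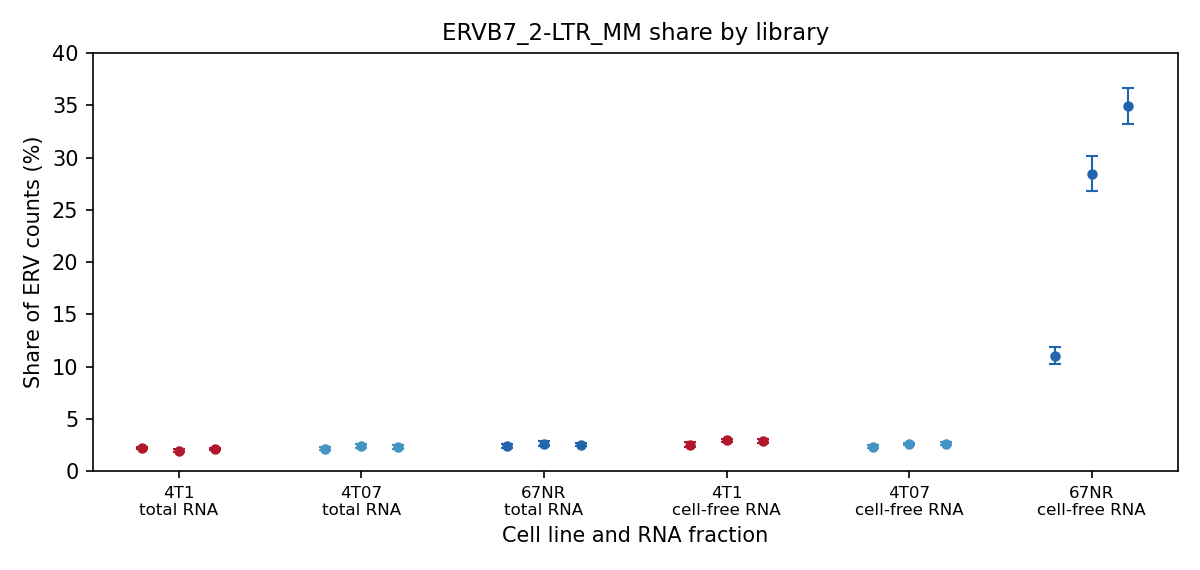
Share of ERV counts that fell on ERVB7_2-LTR_MM (vertical axis, percent) in each mammary library, with Wilson 95% intervals for counting error. The 3 cell-free 67NR libraries lie at 11.03%, 28.5% and 34.9%, and the group means elsewhere lie between 2.11% and 2.79%.

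With edgeR, 0 of 92 entries were higher and 5 lower in cell-free RNA of 4T1 than of 67NR on the ERV-only scale, with 20 at an unadjusted p under 0.05 and 9 lower in DESeq2. The direction of these calls depends on the scale even among ERV counts: without the TMM factor 18 were higher and 2 lower. Without that factor an entry is measured against all ERV counts. ERVB7_2-LTR_MM took 24.8% of these in 67NR and 2.79% in 4T1, which lowers the shares of other entries in 67NR. The 5 became 3 without 4T1 replicate 3, 12 without 67NR replicate 1, 2 without 67NR replicate 2 and 3 without 67NR replicate 3. ERVB3_1-I_MM-int was lower by -1.11 ± 0.23 (edgeR adjusted p 0.0105), a call lost without 67NR replicate 2 (-0.999), and on the authors' scale it was higher by 2.60. On the authors' scale 86 were higher and 1 lower (edgeR, 87 at an unadjusted p under 0.05), which stayed between 82 and 90 in all without each library. When only these 6 libraries were fitted, 49 were higher and 1 lower on that scale. The authors' deposited table has 94 and 1. Of the entries with no counts in 67NR, ERVB4_3-I_MM-int,ERVB4_3-I_MM-int,ERVB4_3-I_MM-int was at least 18.3-fold higher in 4T1 in normalised counts, with 59 counts over its libraries. Values for 67NR rest on libraries of 2716 to 5465 ERV counts.

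Cell-free RNA of 4T07 also held far more of most entries than that of 67NR on the authors' scale. ERVB7_2-LTR_MM was lower in 4T07 relative to the other entries by -3.88 ± 0.54 (SE, n = 3 each; edgeR adjusted p 3.77e-04) and on the authors' scale by -0.79 with an adjusted p of 0.293. ERVB4_1C-LTR_Mm,ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int was lower by -3.35 ± 0.45 (edgeR adjusted p 3.77e-04; -0.99 on the authors' scale; 125 against 68 counts). Both calls were kept without each library. ERVB3_1-I_MM-int was lower by -0.98 ± 0.23 (edgeR adjusted p 0.0243), lost without 4T07 replicate 1 (-0.93) or 3 (-1.03) or 67NR replicate 2 (-0.85) or 3 (-0.85). On the authors' scale it stood at 1.65 with an edgeR adjusted p of 0.0503. With edgeR, 0 of 92 entries were higher and 4 lower on the ERV-only scale, with 11 at an unadjusted p under 0.05 and 6 in DESeq2. The 4 became 2 without 4T07 replicate 1 or 3 or 67NR replicate 2 or 3, and 10 without 67NR replicate 1. On the authors' scale 78 were higher and 0 lower (edgeR, 80 at an unadjusted p under 0.05), 50 without 4T07 replicate 1, and the authors' deposited table has 81 and 0.

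The 4 entries lower in 4T07 than in 67NR were also lower in 4T1 than in 67NR, where 0.217 would be shared by chance. These comparisons share the 67NR libraries, and 100 simulations with no difference gave a mean of 0 shared lower entries. Part of the excess can come from the shared libraries, which are too few to split.

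Between cell-free RNA of 4T1 and 4T07 few entries differed, and all of these were low in counts. ERVB4_1C-LTR_Mm,ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int was lower in 4T1 by -2.36 ± 0.53 (SE, n = 3 each; 18 against 125 counts) and ERVB5_1-I_MM-int,ERVB5_1-I_MM-int,ERVB5_1-LTR_MM was higher by 1.47 ± 0.34 (89 against 45 counts), each with an edgeR adjusted p of 0.0249. They stood at -1.39 and 2.62 on the authors' scale, with adjusted p of 0.303 and 0.0506. The first call was lost without 4T07 replicate 2 (-2.11) or 3 (-2.28) or 4T1 replicate 3 (-2.09) and moved to -3.48 without 4T1 replicate 2, and the second was lost without 4T07 replicate 2 (1.604) or 3 (1.25) or 4T1 replicate 1 (1.21) or 3 (1.62). With edgeR, 1 of 92 entries was higher and 3 were lower, with 8 at an unadjusted p under 0.05 and 3 in DESeq2. The 4 became 0 without 4T07 replicate 2, 4T07 replicate 3 or 4T1 replicate 3, and 2 without 4T1 replicate 1. On the authors' scale 0 were higher and 0 lower with edgeR, 8 had an unadjusted p under 0.05, and the authors' deposited table (DESeq2) has 0 and 0, although the median entry was higher by 1.07. That 0 depends on the fit: 62 were higher on that scale when only these 6 libraries were fitted, and 1 passed with the replicate block.

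The ETn/MusD list took 45.9% ± 14.7 of cell-free ERV counts in 67NR, 27.2% ± 5.12 in 4T07 and 19.1% ± 3.58 in 4T1 (SD, n = 3 each). Its members ERVB7_2-LTR_MM and ERVB7_1-LTR_MM alone took 24.8% and 17.99% in 67NR, 2.53% and 19.3% in 4T07, and 2.79% and 10.1% in 4T1. The higher share in 67NR than in 4T1 is thus carried by these members and not by the list as a whole. Against 4T07 it is carried by ERVB7_2-LTR_MM alone, since ERVB7_1-LTR_MM took a smaller share in 67NR than in 4T07. In total RNA the list took 17.96% ± 0.728, 20.6% ± 0.208 and 18.7% ± 0.295 in 67NR, 4T07 and 4T1, 16.7% ± 0.711 in B16F10 and 13.1% ± 0.940 in B16F0. The exact two-sided permutation p was 0.1, the smallest possible, for 4T1 against 67NR in cell-free RNA, for 4T07 against either line in total RNA and for B16F10 against B16F0, and 0.2 or 0.3 in the others. Without ERVB7_1-LTR_MM the difference turned in 4 comparisons: in percentage points from -1.86 to 0.108 for 4T1 over 4T07, from 2.60 to -0.479 for 4T07 over 67NR and from 0.742 to -0.370 for 4T1 over 67NR in total RNA, and from -8.06 to 0.308 for cell-free 4T1 over 4T07. Internal regions, that is entries whose last name is one, took 57.9% in 67NR, 52.2% in 4T07 and 56.1% in 4T1 total RNA. They took 59.4% in B16F10 and 64.2% in B16F0. In cell-free RNA of 67NR, 4T07 and 4T1 they took 32.9%, 39.98% and 48.5%.

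Within the lists, edgeR counts over all tested entries and those adjusted over the list alone were close. In total RNA of 4T1 against 67NR, 2 of 6 ETn/MusD entries were higher and 1 lower both ways, and of 61 internal regions 4 were higher and 5 lower over all entries against 6 and 5 adjusted over the list alone. Against 4T07 the ETn/MusD counts were 1 and 1 over all entries, 1 and 2 adjusted over the list alone, and of the internal regions 0 and 0 both ways. For 4T07 against 67NR they were 1 and 0 both ways, and 1 and 3 both ways for internal regions. In the melanoma lines they were 2 and 1 both ways, and for 37 internal regions 7 and 10, or 8 and 10 adjusted over the list alone. In cell-free RNA the ETn/MusD counts were 0 and 1 for 4T1 against 67NR (0 and 2 adjusted over the list alone), 0 and 0 both ways for 4T1 against 4T07 and 0 and 1 both ways for 4T07 against 67NR. For 59 internal regions they were 0 and 4 (0 and 5 adjusted over the list alone), 0 and 2 both ways, and 0 and 3 (0 and 4 adjusted over the list alone).

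As sets, neither list differed from the other entries in any of the 7 comparisons by camera, with adjusted p from 0.207 to 0.942 at the preset correlation. With the estimated correlation they also stayed over the threshold. Among the groups added after the names were seen, ERVL entries were lower (camera adjusted p 0.0138) and ERVB4 entries higher (camera adjusted p 0.0439) in B16F10 relative to the other entries, where the median of all entries was 2.26 on the authors' scale. Neither held with the estimated correlation (adjusted p 0.347 each). By fry, which does not compare a list with other entries, ETn/MusD entries were higher in B16F10 (adjusted p 0.0221). The fry values for internal regions in cell-free RNA of 4T1 and 4T07 over 67NR (adjusted p 0.00141 and 8.68e-04) tell nothing about the list, because its medians of 0.26 and 0.28 lay close to those of all tested entries, 0.29 and 0.28.

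Whether the line differences themselves differed between cell-free and total RNA was tested with an interaction term over the 18 mammary libraries. The change of ERVB7_2-LTR_MM from 67NR to 4T1 was lower in cell-free RNA by -3.83 ± 0.51 (SE; edgeR adjusted p 5.38e-05) and that from 67NR to 4T07 by -3.94 ± 0.51 (edgeR adjusted p 3.84e-05). For ERVB4_1C-LTR_Mm,ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int these differences were -4.76 ± 0.69 (edgeR adjusted p 8.59e-05) and -3.47 ± 0.64 (edgeR adjusted p 0.00163). These calls were kept without each library. The differences of ERVB7_2-LTR_MM became -3.19 and -3.23 without 67NR cell-free replicate 3, and the -4.76 became -5.83 without 4T1 cell-free replicate 2. For 4T1 against 67NR, 0 of 96 entries had a higher and 7 a lower change in cell-free RNA (edgeR, 16 at an unadjusted p under 0.05, 5 in DESeq2). DESeq2 left 89 entries without an adjusted p in this contrast. Without the TMM factor 22 had a higher and 4 a lower change, so that the direction of these calls depends on the scale. The 7 became 4 without 67NR total RNA replicate 3, 4T1 cell-free replicate 1 or 67NR cell-free replicate 3, and 11 without 67NR cell-free replicate 1.

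For 4T1 against 4T07 there were 2 and 2 such entries (edgeR, 7 at an unadjusted p under 0.05, 5 in DESeq2), and 2 in all without 4T07 total RNA replicate 3. For 4T07 against 67NR there were 1 and 4 (edgeR, 14 at an unadjusted p under 0.05, 4 in DESeq2). These 5 became 2 without any 1 of the 4T07 total RNA replicates 1, 2 and 3, the 67NR total RNA replicates 2 and 3, the 4T07 cell-free replicates 1 and 3 and the 67NR cell-free replicates 2 and 3. They became 3 without 4T07 cell-free replicate 2 and 11 without 67NR cell-free replicate 1. In summed normalised counts the ratio of 4T07 to 67NR was higher in cell-free than in total RNA by a log2 difference of 2.53 (exact two-sided permutation p 0.02, adjusted 0.06). For 4T1 against 67NR this was 2.88 (permutation p 0.1, adjusted 0.15) and for 4T1 against 4T07 0.35 (permutation p 0.495). The smallest p that the 400 regroupings can give is 0.005, and none of the 3 passed the threshold after adjustment. The regroupings shuffle the lines within each fraction and so assume no line difference in either. They do not test an equal difference in both, and their p depends on the sign of the total RNA difference (0.34 for 4T1 and -0.19 for 4T07 over 67NR).

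Cell-free and total RNA differed in their mix of ERV entries, as a mean over the 3 mammary lines. ERVB7_2-LTR_MM was a larger part in cell-free RNA by 1.73 ± 0.21 (SE; edgeR adjusted p 3.05e-06) and ERVB7_1-LTR_MM by 1.08 ± 0.19 (edgeR adjusted p 1.75e-04), while ERVB4_1B-I_MM-int,ERVB2_1A-I_MM-int was a smaller part by -1.57 ± 0.28 (edgeR adjusted p 1.75e-04). With edgeR 13 of 96 entries were higher and 23 lower, with 46 at an unadjusted p under 0.05 and 38 in DESeq2, and 27 to 36 passed without each library. Without the TMM factor 6 were higher and 49 lower. The calls of these 3 entries were kept without each library. The mean for ERVB7_2-LTR_MM is carried by 67NR, where its share went from 2.53% in total to 24.8% in cell-free RNA, against 2.11% to 2.79% in 4T1 and 2.28% to 2.53% in 4T07. For ERVB7_1-LTR_MM the share went from 8.28% to 17.99% in 67NR, 11.7% to 19.3% in 4T07 and 9.49% to 10.1% in 4T1. Starvation, medium and extraction kit differed between the fractions in the same way, and the authors' size factors were set separately for each, so that this contrast was run on the ERV-only scale alone. Deviations of same-numbered libraries correlated between -0.16 and 0.26 across the fractions, and between 0.064 and 0.26 for 4T07. With 3 libraries per line this cannot tell whether the numbers pair the fractions, and the main fit used no pairing.

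Relative to the other ERV entries, few entries changed alike in the melanoma and the mammary lines. Among 58 entries tested in both, B16F10 over B16F0 and 4T1 over 67NR shared 1 higher entry (0.759 by chance, two-sided Fisher's exact p 1) and 2 lower entries (1.24 by chance, Fisher's exact p 0.594) on the ERV-only scale. By DESeq2, among the 62 entries with an adjusted p in both, they shared 1 higher (0.339 by chance, Fisher's exact p 0.306) and 2 lower (0.71 by chance, Fisher's exact p 0.141). With entries that DESeq2 left without an adjusted p counted too, the 2 lower stood against 0.358 by chance (Fisher's exact p 0.0397). Over the other alternatives on the ERV-only scale the p for lower entries ranged from 0.0938 to 0.296. With 4T1 over 4T07, B16F10 over B16F0 shared 0 and 0 entries called by edgeR (0.19 and 0.414 by chance). On the authors' scale the shared higher entries were 5 (5.48 by chance) with 4T1 over 67NR and 45 (44.8 by chance) with 4T1 over 4T07. There 53 of the 58 entries were called higher in B16F10 over B16F0 and 49 in 4T1 over 4T07. Most entries were thus higher in both, and the chance value takes these numbers as given.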

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

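The edgeR interaction terms were planned, while the permutation test of summed counts between fractions, the look for opposite directions and every test of an explanation or of other groupings given here were chosen after the result was seen. Single libraries were not tested as outliers.

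For some entries the change between 2 lines differed between cell-free and total RNA. From 67NR to 4T1 the log2 change was lower in cell-free RNA by -3.83 for ERVB7_2-LTR_MM (edgeR adjusted p 5.38e-05) and by -4.76 for ERVB4_1C-LTR_Mm,ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int (edgeR adjusted p 8.59e-05). Both calls were kept without each library, at -3.19 for the first without 67NR cell-free replicate 3 and -5.83 for the second without 4T1 cell-free replicate 2. For ERVB4_1-I_MM-int,ERVB4_1B-I_MM-int it was lower by -2.48 (edgeR adjusted p 0.00700), lost without 67NR cell-free replicate 1 (-2.55). ERVB7_1-LTR_MM was lower by -1.88 (edgeR adjusted p 0.0153), lost without 67NR total RNA replicate 3 (-1.69), 4T1 cell-free replicate 1 (-1.58) or 67NR cell-free replicate 2 (-1.63) or 3 (-1.48). ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int was lower by -1.29 (edgeR adjusted p 0.0270). That call was lost without 4T1 total RNA replicate 1 (-1.21), 2 (-1.27) or 3 (-1.197), 67NR total RNA replicate 3 (-1.19), 4T1 cell-free replicate 1 (-1.24) or 2 (-1.24), or 67NR cell-free replicate 2 (-1.01) or 3 (-0.76).

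Between 4T07 and 4T1 the change was lower in cell-free RNA by -1.54 for ERVB4_1-I_MM-int,ERVB4_1B-I_MM-int and higher by 1.73 for ERVB5_1-I_MM-int,ERVB5_1-I_MM-int,ERVB5_1-LTR_MM, both with an edgeR adjusted p of 0.0101 and both kept without each library. It was higher by 1.59 for ERVB5_2-LTR_MM,ERVB5_1-I_MM-int,ERVB5_1-I_MM-int,ERVB5_1-I_MM-int (edgeR adjusted p 0.0101), lost without 4T07 total RNA replicate 3 (1.37). For ERVB4_1B-I_MM-int,ERVB4_1B-LTR_MM,ERVB4_1B-I_MM-int it was lower by -1.70 (edgeR adjusted p 0.0270), lost without 4T07 total RNA replicate 3 (-1.57), 4T07 cell-free replicate 2 (-1.52) or 4T1 cell-free replicate 2 (-1.82) or 3 (-1.76). These entries had 15 to 129 counts over the 3 cell-free libraries of either line.

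From 67NR to 4T07 the change was lower in cell-free RNA by -3.94 for ERVB7_2-LTR_MM (edgeR adjusted p 3.84e-05) and by -3.47 for ERVB4_1C-LTR_Mm,ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int (edgeR adjusted p 0.00163), both kept without each library, the first at -3.23 without 67NR cell-free replicate 3. For ERVB4_1B-LTR_MM,ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int,ERVB4_1B-LTR_MM the fitted difference was 7.89 (edgeR adjusted p 0.0428), which is no measured fold, since 67NR cell-free RNA had 0 counts against 72 in 4T07. ERVB4_1B-I_MM-int was lower by -0.97 (edgeR adjusted p 0.0428) and ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int by -1.25 (edgeR adjusted p 0.0452). The first of these last 3 calls was lost without any library other than 67NR total RNA replicate 1 or 4T07 cell-free replicate 2 (fitted values 7.65 to 8.05). The other 2 were lost without any library other than 67NR total RNA replicate 1 or 67NR cell-free replicate 1, and ERVB4_1B-I_MM-int reached -0.63 and ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int -0.65, both without 67NR cell-free replicate 3. In summed normalised counts the log2 difference between 4T07 and 67NR was higher in cell-free RNA by 2.53 (exact permutation p 0.02, adjusted 0.06). That permutation assumes no line difference in either fraction and does not test an equal difference in both.

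Other groupings were set against the real one for these counts. For the differences of line effects they shuffle the lines within each fraction and so assume no line difference in either. They cannot tell chance from an equal line difference in both fractions, so that chance stays open for these differences whatever the share. For 4T1 against 67NR, 6 of 100 regroupings, the real one included, gave as many entries as the real 7, with 9 the highest of the others, so that chance cannot be excluded. That highest count came where the lines stayed whole and traded places in 1 fraction. For 4T07 against 67NR, 8 of 100 gave as many as the real 5, with 6 the highest of the others, so that chance cannot be excluded there either. For 4T1 against 4T07, 3 of 100 gave as many as the real 4, with 4 the highest of the others, a share under 0.05. Same-numbered cell-free libraries of these lines correlated, but replicates 2 and 3 did as much across numbers (0.182 and 0.166), so that a pairing is unsure. If the numbers pair them, the regroupings that part all 3 pairs are the closer comparison. Of the 32 drawn besides the real one 2 gave as many, so that chance is not excluded among them. For cell-free against total RNA only the real grouping (1 of 100) gave as many as 36, with 5 the highest of the others, so that chance can be excluded at the 0.05 level.

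Some named entries differed between the melanoma lines in the opposite direction to the mammary lines, with no overlap of single libraries in either, and the difference itself was not tested. Of 58 entries tested in both, 13 had no overlap in the melanoma lines and in 4T1 against 67NR, of which 7 went opposite ways, and 13 had none in the melanoma lines and in 4T1 against 4T07, of which 9 did. Since the ERV-only scale centres the changes near 0, many opposite directions can arise by chance. On that scale ERVB4_1B-LTR_MM was at -0.73 in B16F10 over B16F0 and 0.14 in 4T1 over 67NR, and ERVB7_2B-LTR_MM at 0.34 against -0.11 in 4T1 over 67NR and -0.13 in 4T1 over 4T07. None of these mammary values passed the threshold (edgeR adjusted p 0.231 for ERVB7_2B-LTR_MM in 4T1 over 4T07). ERVB7_1-LTR_MM was at 0.50 in B16F10 over B16F0 against -0.38 in 4T1 over 4T07, and ERVB4_1C-LTR_Mm at 0.46 against -0.58. B16F10 over B16F0 was positive on the authors' scale for all 4, and so was 4T1 over 4T07 for ERVB7_2B-LTR_MM (0.48), ERVB7_1-LTR_MM (0.23) and ERVB4_1C-LTR_Mm (0.026). Mean normalised counts in total RNA were also higher in 4T1 than in 67NR. They were 1695 ± 68.7 against 1518 ± 303 for ERVB7_2B-LTR_MM and 3492 ± 272 against 2636 ± 581 for ERVB4_1B-LTR_MM (SD, n = 3 each). The call of ERVB4_1B-LTR_MM in B16F10 was lost without B16F0 replicate 2 (-0.57) or B16F10 replicate 1 (-0.6996) or 2 (-0.696). That of ERVB7_2B-LTR_MM was lost without B16F0 replicate 2 (0.29) or 3 (0.18) or B16F10 replicate 1 (0.304) or 3 (0.34), that of ERVB7_1-LTR_MM without B16F0 replicate 2 (0.45) or 3 (0.41), and that of ERVB4_1C-LTR_Mm without B16F0 replicate 2 (0.32) or 3 (0.34) or B16F10 replicate 1 (0.42).

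A larger part of the cell-free ERV counts fell on ERVB7_2-LTR_MM in 67NR than in 4T1 or 4T07. Counting error is argued against, since the lowest lower limit among the 67NR libraries was 10.2% and the highest share among the 6 others was 2.95%. An equal normalised background of this entry in all libraries is argued against too, if the authors' size factors hold: it can be no higher than the counts in 4T07 (771 at most), and with that much taken off everywhere the lowest lower limit in 67NR was 2.92% against a highest share of 1.25% elsewhere. Metastatic capacity as the labels class it is argued against as the whole cause by the difference of -3.88 between the poorly metastatic lines. The labels do not rank these lines, so that a graded capacity stays open. A foreign source in the 67NR medium, multiple alignments and line biology stay open, and since this entry differed by 0.21 on the authors' scale, a lack of the other entries in 67NR may describe it as well.

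Summed normalised ERV counts were higher in 4T1 and 4T07 than in 67NR cell-free RNA and in B16F10 than in B16F0. The log2 ratios of the size factors, 0.11 for B16F10, -0.12 for 4T1 and 1.59 for 4T07, decide nothing about depth, because the sums are already divided by these factors. A size factor set too small in the higher line would raise its sum, and since the depth beyond the ERV entries is not given, this stays open for all 3 differences. A single added source such as genomic DNA could fit, because the counts added in 4T1 and in B16F10 had a like make-up (Spearman 0.948), but they also resembled the libraries they were added to (0.886 and 0.923), which leaves it open. If the size factors hold, metastatic capacity as the labels class it is argued against as the whole cause in cell-free RNA by the 5.09-fold difference in geometric means between the poorly metastatic lines. What set these factors is unknown. The labels do not rank the poorly metastatic lines, and the sums rose from 67NR over 4T07 to 4T1, so that a graded capacity stays open.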

How the results depend on the processing

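The alternatives run on the authors' scale were chosen after the data were seen, except the authors' size factors themselves. With the authors' size factors in place of TMM, which keep a change shared by all entries, the count went from 13 to 8 for 4T1 over 67NR, from 3 to 63 for 4T1 over 4T07, from 6 to 11 for 4T07 over 67NR and from 23 to 53 for B16F10 over B16F0 in total RNA. In cell-free RNA it went from 5 to 87, from 4 to 0 (edgeR, 8 at an unadjusted p under 0.05 on both scales; DESeq2 3) and from 4 to 78.

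Of the named values, 30 changed sign with a call before or after, all with the authors' size factors, while sign changes with no call on either side, 57 in number, came with other settings too. For 4T1 over 67NR in total RNA, ERVB7_2-LTR_MM went from -0.21 to 0.049 and ERVB4_3-LTR_MM from -0.20 to 0.052. For 4T1 over 4T07, ERVB7_1-LTR_MM went from -0.38 to 0.23, ERVB4_1C-LTR_Mm from -0.58 to 0.026, ERVB7_2-LTR_MM from -0.19 to 0.41, ERVB7_2B-LTR_MM from -0.13 to 0.48 and ERVL-E-int from -0.058 to 0.54. In B16F10 over B16F0 the value became 1.29 for ERVB2_1A-I_MM-int, 1.40 for ERVB3_1-I_MM-int, 1.29 for ERVL-B4-int,ERVL-B4-int, 1.59 for ERVB7_2-LTR_MM, 1.84 for ERVL-int, 1.82 for ERVB4_1B-I_MM-int, 1.69 for ERVL-B4-int and 1.62 for ERVB4_1B-LTR_MM. It became 0.999 for ERVB3_1-I_MM-int,ERVB3_1-I_MM-int, 1.73 for ERVB2_1-I_MM-int, 1.95 for ERVL-E-int and 2.10 for ERV3-16A3_I-int, all negative on the ERV-only scale. In cell-free RNA of 4T1 over 67NR it became 0.21 for ERVB7_2-LTR_MM, 2.60 for ERVB3_1-I_MM-int, 2.76 for ERVB4_1B-I_MM-int, 2.63 for ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int, 2.33 for ERVB7_1-LTR_MM, 3.21 for ERVB4_1C-LTR_Mm and 3.35 for ERVL-B4-int. In 4T07 over 67NR it became 1.65 for ERVB3_1-I_MM-int, 1.47 for ERVB4_1B-I_MM-int,ERVB4_1B-I_MM-int, 2.37 for ERVB7_1-LTR_MM and 2.255 for ERVL-B4-int.

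Without the TMM factor the count went from 3 to 18 (15 higher, 3 lower) for 4T1 over 4T07 and from 6 to 13 (3 higher, 10 lower) for 4T07 over 67NR in total RNA. In cell-free RNA it went from 5, all lower, to 20 (18 higher, 2 lower) for 4T1 over 67NR, from 4 to 2 for 4T1 over 4T07 and from 4 to 2 for 4T07 over 67NR. It went from 7, all lower, to 26 (22 higher, 4 lower) for the interaction of 4T1 with 67NR, from 36 (13 higher, 23 lower) to 55 (6 higher, 49 lower) for cell-free against total RNA and from 3 to 5 for entries shared by the melanoma and mammary comparisons. The cause was not tested. DESeq2 called 7 in place of 13 for 4T1 over 67NR in total RNA and 9 in place of 5 in cell-free RNA, and RLE factors gave 2 in place of 5 for the interaction of 4T07 with 67NR. In these too the cause was not tested.

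With no filter, which adds entries to the adjustment, 14 (3 higher, 11 lower) in place of 23 (11 higher, 12 lower) passed in B16F10 over B16F0, 4 in place of 7 in the interaction of 4T1 with 67NR and 2 in place of 5 in that of 4T07 with 67NR. A mean of 50 or more counts, with fewer entries tested, gave 6 in place of 3 for 4T1 over 4T07 in total RNA, 3 in place of 5 for cell-free 4T1 over 67NR and 0 in place of 4 with edgeR for cell-free 4T1 over 4T07, where 8 had an unadjusted p under 0.05 before the low entries were taken out and DESeq2 called 3. The replicate block gave 12 (4 higher, 8 lower) in place of 23 in B16F10 over B16F0 and 2 in place of 5 in the interaction of 4T07 with 67NR, and the cause was not tested. A fit of only the 6 libraries compared, which has fewer samples, gave 8 in place of 13 for 4T1 over 67NR and 5 in place of 3 for 4T1 over 4T07 in total RNA, and 2 in place of 5 and 2 in place of 4 for cell-free 4T1 and 4T07 over 67NR.

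The fit of only 6 libraries gave, on the authors' scale, 1 in place of 8 for 4T1 over 67NR and 2 in place of 11 for 4T07 over 67NR in total RNA, 50 in place of 87 for cell-free 4T1 over 67NR and 62 in place of 0 for cell-free 4T1 over 4T07. The block gave 6 in place of 11 for 4T07 over 67NR in total RNA and 1 in place of 0 for cell-free 4T1 over 4T07, and no filter gave 6 in place of 11 for 4T07 over 67NR in total RNA. For the block the cause was not tested.

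Without each library in turn, the count on the ERV-only scale ranged from 6 to 14 for 4T1 over 67NR, 1 to 4 for 4T1 over 4T07, 2 to 7 for 4T07 over 67NR and 9 to 23 for B16F10 over B16F0 in total RNA. In cell-free RNA it ranged from 2 to 12, 0 to 4 and 2 to 10 for the 3 mammary comparisons in the same order. It ranged from 4 to 11, 2 to 5 and 2 to 11 for their interactions and from 27 to 36 for cell-free against total RNA. With the authors' size factors it ranged from 0 to 58, 38 to 57, 0 to 54 and 0 to 63 in total RNA and from 82 to 90, 0 to 0 and 50 to 88 in cell-free RNA. The single libraries behind these changes are those named with each comparison. The log2 difference of summed counts kept its direction without each library, between 0.21 and 0.48, 0.50 and 0.55, -0.31 and -0.044, and 1.63 and 2.46 in total RNA and between 2.90 and 3.75, 0.76 and 1.07, and 2.04 and 2.88 in cell-free RNA. The value nearest 0, -0.044 in place of -0.19 for 4T07 over 67NR, came without 67NR replicate 3.

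The shares of both lists kept their direction without each library. ERVB7_1-LTR_MM had the most counts over all mammary libraries of each fraction, though it was not first in every line. Without it the ETn/MusD difference in percentage points went from 0.742 to -0.370 for 4T1 over 67NR, from -1.86 to 0.108 for 4T1 over 4T07 and from 2.60 to -0.479 for 4T07 over 67NR in total RNA, and from -8.06 to 0.308 for cell-free 4T1 over 4T07, so that these differences rest on that entry.

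Of 1965 other values for the 137 named results, 1557 kept direction and side of the threshold, 266 lost and 55 gained a call in the same direction, and 57 changed sign with a call neither before nor after. The 14 list tests kept direction and side with RLE factors, without the TMM factor and with the estimated correlation. With the block 1 changed direction, and with fry 3 gained a call and 3 changed direction, which fry by its construction can do since it does not compare a list with other entries.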

Other observations

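The tests given here, of other groupings and of explanations for ERVB7_1-LTR_MM, were chosen after the results were seen.

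Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. On the ERV-only scale in total RNA only the real split (1 of 10) gave as many entries: 13 for 4T1 over 67NR with 2 the highest of the others, 3 for 4T1 over 4T07 with 0, 6 for 4T07 over 67NR with 0, and 23 for B16F10 over B16F0 with 0. In cell-free RNA the real split gave 5 with 2 the highest of the others, 4 with 0 and 4 with 0 for the 3 mammary comparisons. With the authors' size factors it gave 8 with 0, 63 with 0, 11 with 1 and 53 with 0 in total RNA, and 87 with 0 and 78 with 0 for cell-free 4T1 and 4T07 over 67NR. For cell-free 4T1 over 4T07 on that scale all 10 splits gave 0 entries (edgeR, 8 at an unadjusted p under 0.05 in the real one). In the comparison of cell-free 4T1 with 4T07, where deviations of same-numbered libraries correlated at 0.152 or more, the splits that part all 3 pairs other than the real one also gave 0 on both scales.

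ERVB7_1-LTR_MM took a larger part of the ERV counts in 4T07 total RNA than in 67NR or 4T1, relative to the other entries. With the 2 leading entries out of the scaling step the log2 change from 67NR was 0.66 ± 0.054 in place of 0.63 ± 0.061 (SE). That decides little about a shift of the scale by a few abundant entries, because TMM by its construction already leaves out the most extreme changes. Reads moved between ERVB7 names in counting are argued against as the whole cause, since all ERVB7 names together gained 2.60 percentage points and ERVB7_1-LTR_MM alone 3.38. Metastatic capacity as the labels class it is argued against as the whole cause, because 4T07 and 67NR are both called poorly metastatic and differed by 0.63. A shift of the scale, reads moved from names outside ERVB7, the origin of the size factors, by which the change was 0.31, and line biology stay open.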
